A study of Mus musculus with 5 samples.

How the data were processed

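Mouse embryonic fibroblasts were sampled on days 0, 1.5, 3, 4.5 and 6 of a sequential retroviral delivery of 4 factors, with 1 array per day and 5 arrays in all. Per the labels' protocols, the fibroblasts came from 13.5-day embryos, virus supernatant was collected from packaging cells at 24 and 48 h, and cells were kept in 10% serum. Samples were grouped by the day in their labels. The labels do not state whether RNA was taken before or after the virus of that day.

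The intensity values are the processed and median signals of single-colour Agilent arrays, written by Feature Extraction 10.7.3.1 per the file headers, and by version 10.7 per the submitters' processing notes. Per the file headers that software subtracted background and spatial trends from the processed signals and put small values at a floor, without scaling between arrays. The deposited series table holds log2 values in which the 5 columns had medians of 6.04 each. The authors' steps in making these log2 values are not given in the sources used here. Set against the arrays, each column correlated best with its own array, with r of at least 0.998 across probes, and at the same rank the columns differed by at most 0.0094 over 41267 probes, as quantile normalized columns would. Their centring and the background steps behind them stay unknown, and they served as an alternative only.

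Each array had 45018 spots, of which 43379 were not controls, and 41174 probes, of which 40929 had 1 spot and 245 had 10. Control spots and spots marked as outliers by the software (67 to 93 per array) were left out, and 0 spots were saturated. Processed signals were taken as log2 values, spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. That percentile was 9.53, 9.56, 9.57, 9.10 and 9.42 in log2 on days 0, 1.5, 3, 4.5 and 6. Signal over background limits the precision for dim probes, and the number of arrays limits it for all.

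Probes were named through the accession in the files, matched without version to a RefSeq gene table of assembly GRCm38.p6, from which names only were used. In all 27479 probes matched 1 symbol and 13695 had none, giving 18749 symbols, of which 6641 had several probes. A gene was represented by the probe with the highest mean level among its probes well above background on at least 1 array. On day 6 against day 0, 5149 genes had several probes well above background on both arrays, 1501 of these had a probe at least 2-fold different, and in 17 of them probes were at least 2-fold different in opposite directions.

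Days 1.5, 3, 4.5 and 6 were compared with day 0, and consecutive days with each other. With 1 array per day no test was possible and no p-value is given. Genes were counted when their log2 difference reached 2-fold and they were well above background on both arrays. A gene well above background on only 1 of the 2 arrays has a bound: its level there against the higher of its own level and the lowest level well above background on the other array, written as at least N-fold. Bounds of at least 2-fold were found for 183 higher and 177 lower genes on day 1.5 and for 313 higher and 393 lower genes on day 6 against day 0.

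For 28 gene lists fixed before the data were examined, the median log2 difference was set among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. This percentile describes these arrays and is no p-value, and the 28 lists on 4 days form 1 family. Members not well above background entered at their measured values, and the medians with such members at their bound were an alternative. There a dim value was raised to the lowest level well above background on its array where it lay below that level. A member dim on both arrays can then carry the difference between those lowest levels, which is no bound of its change. The lists were: delivered factors; mesenchymal and EMT genes, epithelial genes, TGF-beta genes, fibroblast and matrix genes; early pluripotency-associated genes and the core pluripotency network; S phase, G2/M, p53 and senescence, interferon and antiviral, and inflammatory genes. The others were glycolysis, oxidative phosphorylation, ribosome biogenesis, chromatin and DNA methylation, Bmp and Wnt, cholesterol synthesis, and unfolded protein and stress response genes, and markers of muscle, macrophages and blood cells, endothelium, neurons and glia, endoderm, mesoderm and trophoblast, adipocytes, cartilage and bone, and keratinocytes, with ribosomal protein and housekeeping genes as controls.

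The genes named were set by a rule fixed before the data were examined. It took the 10 measured genes furthest up and down against day 0, the 5 with the largest bounds in each direction and the 5 furthest in each direction at each step. It added the 4 delivered factors, up to 3 members of each list in each direction on each day, and a few fixed marker genes of the mesenchymal, epithelial and pluripotency lists. Clone and predicted names were excluded, and some genes that the rule names are not reported here.

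Alternatives were quantile normalization, median scaling, scaling to 8 spike-in probes, no scaling, the authors' deposited values, the mean over probes of a gene, other filters on dim probes, thresholds of 1.5-fold and 3-fold, counting probes, and random lists not matched on expression. A normexp background correction with an offset of 50 was planned on mean signals, a column that the files used here do not hold, and was run on the median signals and local background medians, a choice made after seeing the data. The offset is added to every signal, which shrinks the differences of dim probes whatever their cause. The probe chosen for a gene was kept in all alternatives but the mean over probes and the count of probes. That count also took in probes without a symbol. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the normexp correction with limma 3.58.1 in R 4.3.3.

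The steps were tested on simulated data for day 1.5 against day 0. Each simulated array held the day 0 levels with independent noise of the software's spot error, without slide, labelling or biological variation. The shares below test the steps and are no error rates for comparisons between these arrays. Of 50 genes each changed by 1.5-, 2-, 3- and 4-fold, 4%, 44%, 98% and 100% were counted, and 3 of 14046 unchanged genes were counted among the 14246. Of 100 unchanged lists run on 15811 genes, 3 lay outside the central 95% of random lists, and a list shifted by 0.5 lay at percentile 100.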

Results

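Gene expression was measured in mouse embryonic fibroblasts, taken from 13.5-day embryos and carrying an Oct4-GFP allele, while they were infected in sequence with retroviruses for 4 reprogramming factors. Oct4 (Pou5f1) and Klf4 were delivered on day 0, Oct4, Klf4 and c-Myc on day 1.5, c-Myc and Sox2 on day 3, and Sox2 on day 4.5. RNA from days 0, 1.5, 3, 4.5 and 6 was hybridised to 1 single-colour array per day. The labels do not say whether RNA of a day was taken before or after that day's virus. With 1 array per day there was no spread between replicates, and no difference below has a replicate check or a p-value. The error estimates are technical. The median spot error of a log2 difference, taken from the error the software gives for each spot, was 0.204 in every comparison. It is the software's estimate, and not a spread measured between spots or arrays. Replicate spots of a probe had a root mean square SD of 0.110 to 0.138 within an array. The 8 spike-in probes had a mean SD of 0.114 over the 5 arrays. The arrays lay on 3 slides, with day 0 alone on the first, days 1.5 and 3 on the second and days 4.5 and 6 on the third. Slide and day therefore cannot be told apart in any comparison with day 0 or between days 3 and 4.5, and values for day 3 against day 1.5 and day 6 against day 4.5 are the within-slide ones. Probes well above background made up 68.9% on day 0, 73.0% on day 1.5, 72.6% on day 3, 64.4% on day 4.5 and 69.5% on day 6. Of the genes with a symbol, 15811 were measured. All differences are log2 values, the later day minus the earlier.

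Among the probes of the delivered factors, Klf4 was already bright on day 0 and was 2.21-fold higher on day 1.5, 2.44-fold on day 3, 3.05-fold on day 4.5 and 2.06-fold on day 6. Myc was covered by 3 probes, which disagreed. Probe A_52_P108346, used for the gene because it was brightest, was at -0.38 on day 1.5 and then at 1.27, 1.38 and 0.97 on days 3, 4.5 and 6. Probe A_52_P278549 followed it, with -0.43, 1.94, 2.17 and 1.76, whereas probe A_51_P102096 went down, with -0.27, -1.31, -1.51 and -2.02. Sox2 was well above background on all 5 arrays, though at low signals, and stood at 0.29, 0.27, -0.24 and 0.61. Pou5f1 was well above background only on day 1.5, with a processed signal of 11.5 against 6.60 on day 0. Whether a probe lies in the part of the transcript that the viruses carried is not known here, so the Pou5f1 and Sox2 values check nothing about delivery.

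**Figure D1:**
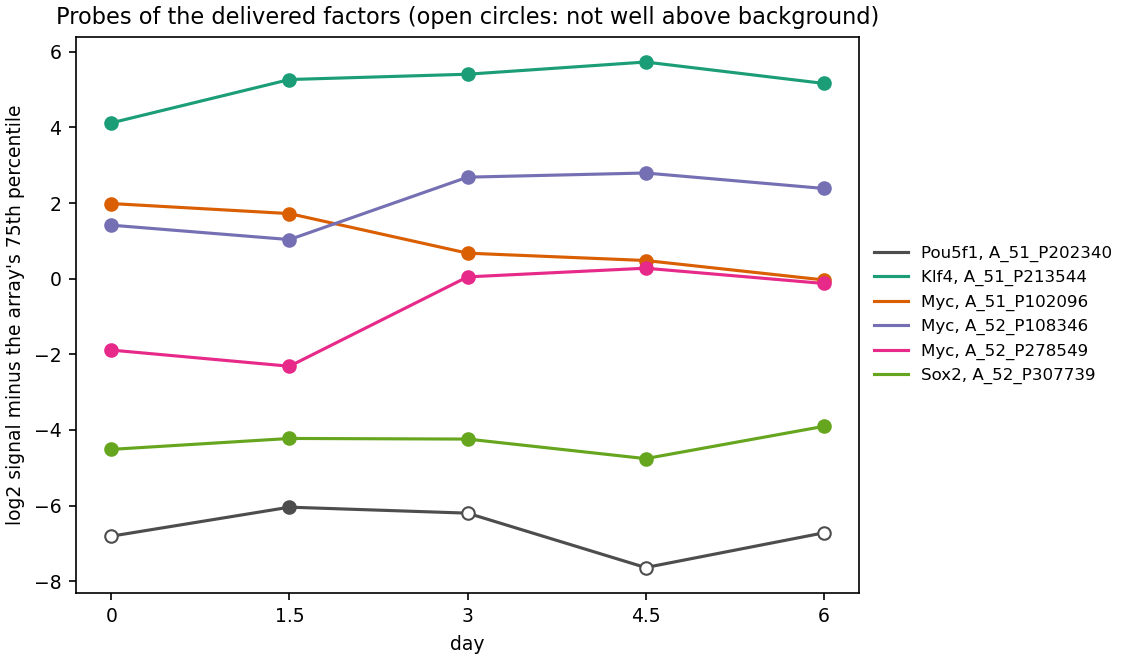
Level of each probe of the 4 delivered factors against day, as log2 signal minus the array's 75th percentile, with 1 array per day and open circles where the probe was not well above background. The 3 Myc probes differ in level on day 0 and change alike to day 1.5. From day 1.5 to day 3 probe A_51_P102096 falls and the others rise.

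The number of genes at least 2-fold different from day 0 grew with time, except that without scaling it was smaller on day 6 (1252 higher, 2283 lower) than on day 4.5 (705 higher, 3120 lower). With the 75th percentile scaling it was 1080 of 14246 genes on day 1.5 (650 higher, 430 lower), 2005 of 14167 on day 3 (1030 higher, 975 lower), 2678 of 13257 on day 4.5 (1220 higher, 1458 lower) and 3400 of 13774 on day 6 (1453 higher, 1947 lower). Between consecutive days the numbers were smaller. Within the second slide, 399 genes were higher and 297 lower on day 3 than on day 1.5. Between slides, 108 were higher and 301 lower on day 4.5 than on day 3. Within the third slide, 114 were higher and 80 lower on day 6 than on day 4.5. The order of the 3 steps changed without scaling (695, 1153 and 365 genes) and without the filter on dim probes (1106, 1408 and 748). Normexp correction, run on median signals, gave counts more than 1.5 times smaller, with 513, 1230, 1668 and 2155 genes against day 0. Its offset shrinks the differences of dim genes. The counts also depended on the filter on dim probes, without which 1861 genes passed on day 1.5 and 4210 on day 4.5.

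The share of higher genes depended on how the arrays were scaled. Median, spike-in and no scaling differ from the 75th percentile scaling by 1 constant for all genes of a comparison, so they can turn the sign of a list's median and cannot move its place among random lists. Scaling to the spike-in probes turned the share of higher genes from 51.4% to 62.6% on day 3, from 45.6% to 61.8% on day 4.5 and from 42.7% to 63.2% on day 6. It moved the share from 26.4% to 39.4% for day 4.5 against day 3 and from 58.8% to 69.9% for day 6 against day 4.5. Median scaling gave 38.9% on day 3 against day 0, 44.4% for day 3 against day 1.5 in place of 57.3%, and 57.5% for day 4.5 against day 3. For that last step quantile normalization gave 52.6%, the authors' deposited values 52.4% and normexp correction 43.7%, and normexp correction gave 76.4% for day 6 against day 4.5. Unscaled signals gave 18.4% for day 4.5 against day 0, 2.78% for day 4.5 against day 3 and 91.5% for day 6 against day 4.5. Against these settings the median of all genes shifted: with spike-in scaling it lay at 0.13 on day 4.5 and 0.18 on day 6, and with median scaling at -0.18 on day 3 against day 0, -0.15 for day 3 against day 1.5 and 0.17 for day 4.5 against day 3. Without scaling it lay at -0.51 on day 4.5 and -0.21 on day 6 against day 0, -0.48 for day 4.5 against day 3 and 0.33 for day 6 against day 4.5.

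**Figure D2:**
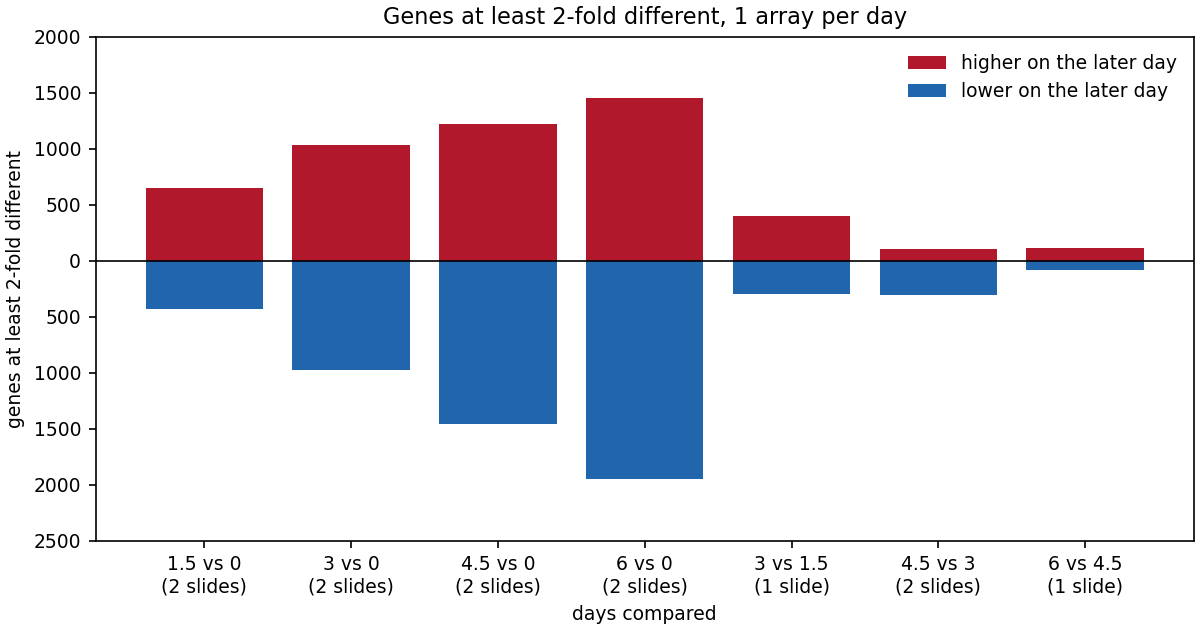
Genes at least 2-fold higher (up) or lower (down) on the later day, for each pair of days, with 1 array per day. Counts against day 0 grow from 1080 to 3400, and the last step, day 6 against day 4.5, has 194.

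On day 1.5 the genes furthest above day 0 included genes of neurons and of stratified epithelium. Nefm and Nefl, the medium and light neurofilament subunits, were 52.1-fold and 46.3-fold higher, and Nts, the precursor of neurotensin, 50.6-fold. Krtdap, a keratinocyte differentiation gene, was 46.9-fold higher, Ly6d 35.0-fold and Slurp1 34.5-fold. Bglap, which encodes osteocalcin, was 33.4-fold higher, Cited1 38.5-fold and the protocadherin Pcdh10 35.9-fold. Cbln2 was not well above background on day 0 and was at least 174-fold higher, and Tek, an endothelial receptor tyrosine kinase, at least 27.8-fold. Among the genes furthest below day 0 were the receptor genes Gpr17 (17.8-fold lower), Il20ra (10.1-fold) and Il1rl1 (7.99-fold). The chemokine genes Ccl11 and Ccl8 were 10.0-fold and 7.41-fold lower, and the muscle myosin light chain gene Myl1 7.63-fold. Gpr17 and Ccl11 were well above background but at low levels on day 1.5, of -5.78 and -5.88. So were Krtdap and Ly6d on day 0, at -5.42 and -5.46.

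On day 3, after c-Myc had been added, Bglap was 254-fold above day 0, Slurp1 148-fold, Krtdap 111-fold, Nts 109-fold and Nefm 88.6-fold. Scara5 was 60.5-fold higher and Pcdh10 65.4-fold. Hbb-bt, an adult beta-globin gene, and Oas2, an antiviral enzyme, were at least 54.5-fold and 48.8-fold higher. Slco4a1 was at -4.32 and Il1rl1 was 15.8-fold lower, the embryonic myosin gene Myh3 12.8-fold and Il1rn, the interleukin 1 receptor antagonist, 11.1-fold. Tnfsf11, which encodes the osteoclast factor RANKL, was at -3.46. Slco4a1, Myh3 and Tnfsf11 were well above background but at low levels on day 3, of -5.69, -6.12 and -6.13. In the within-slide step from day 1.5, Chrdl1 (13.8-fold), Mctp1 (9.81-fold), Hbb-bt (9.79-fold) and Oas2 (7.80-fold) were among the 5 genes furthest up. Tas2r135 (8.06-fold) and Npas1 (7.56-fold) were the furthest down. Mctp1 had a low level on day 1.5, -5.78, and Tas2r135 and Npas1 had low levels on day 3, -5.88 and -5.76.

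On day 4.5, after the first Sox2 delivery, Bglap was 283-fold, Slurp1 207-fold and Ifi27l2a, an interferon-inducible gene, 115-fold above day 0. Gng13, a G protein gamma subunit, was 103-fold higher. Cbln2 was at least 636-fold and Hbb-bt at least 270-fold higher. Among genes measured on both arrays the furthest down were Myl1 (23.0-fold), Il1rl1 (22.9-fold) and Mogat2 (18.0-fold), with the chemokine Cxcl5 (14.8-fold) and Il6 (13.9-fold) also among the 10 furthest down. Jakmip2 and Lin7a, not well above background on day 4.5, were at least 23.6-fold and 18.4-fold lower. Emcn, an endothelial sialomucin, was 13.5-fold lower and Actc1, cardiac actin, 12.4-fold. Against day 3, on the other slide, Tex33 (8.88-fold), Uhrf1bp1 (8.73-fold) and Akr1c18 (6.42-fold) were higher. Cyp2c37 (10.5-fold), Tmem245 (8.84-fold) and the ribosomal protein gene Rpl30 (5.51-fold) were lower. Tex33 and Akr1c18 had low levels on day 3, -5.97 and -6.24.

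On day 6, Bglap was 305-fold, Slurp1 284-fold, Gng13 219-fold, Ly6d 165-fold and Krtdap 142-fold above day 0. Tnxb, which encodes the matrix protein tenascin-X, was 164-fold higher, Lbp, the lipopolysaccharide-binding protein, 137-fold and Pi16 129-fold. Tnxb, Ly6d and Krtdap were well above background but at low levels on day 0, of -5.41, -5.46 and -5.42. Oas2 was at least 291-fold and Cbln2 at least 823-fold higher. Il1rl1 was 37.8-fold, Cthrc1 33.3-fold, Il6 22.4-fold and the tendon gene Tnmd 20.7-fold lower, and Cnn1, smooth muscle calponin, 19.7-fold. Within the slide, against day 4.5, Akr1c18 (11.9-fold) and Csn1s1 (8.70-fold) were the furthest up. Uhrf1bp1 (11.4-fold), Foxq1 (8.03-fold) and the Wnt antagonist Dkk1 (5.87-fold) were among the furthest down. Uhrf1bp1 and Tmem245 thus moved one way on day 4.5 and back on day 6. Both moves rest on the day 4.5 array, where replicate spots had the highest root mean square SD, 0.138. Bglap and Bglap3, and the globin genes, are near-identical families, and which copy a probe measured is uncertain.

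The order of delivery raises the question of when mesenchymal genes and epithelial genes move on the way to pluripotency. The 29 measured mesenchymal and EMT genes had a median of -0.10 on day 1.5, -0.19 on day 3, -0.27 on day 4.5 and -0.52 on day 6. Only the day 6 value lay outside the central 95% of 10000 matched random lists (-0.34 to 0.20). With spike-in scaling days 4.5 and 6 were at -0.065 and -0.24. The day 4.5 median was -0.70 without scaling and -0.47 with the mean over probes. On day 1.5, 1 member was at least 2-fold higher, the surface receptor Cd44 (1.06), and 1 lower, Mmp3 (-1.69). On day 6, 10 were lower and 1 higher. The smooth muscle genes Acta2 (-3.03) and Tagln (-2.24) and N-cadherin, Cdh2 (-2.01), were among the lower ones, and the gelatinase Mmp2 (1.57) was the higher one. Among the transcription factors of this program, Snai2 stood at -0.17, -0.86, -1.06 and -1.78 and Snai1 at -0.58, -0.08, -0.47 and -1.24, while Zeb1 and Zeb2 lay between 0.06 and 0.31 on all 4 days. The within-slide medians were -0.09 for day 3 against day 1.5 and -0.16 for day 6 against day 4.5, the latter at 0.17 without scaling and at percentile 0.05 of random lists.

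The 29 measured epithelial genes had medians of 0.34, 0.32, 0.01 and 0.31 on the 4 days, against ranges of random lists of -0.21 to 0.26, -0.32 to 0.31, -0.69 to 0.19 and -0.70 to 0.21. With dim members set at their bound the day 6 median turned to -0.21, and normexp correction left 0.05 on day 1.5 and 0.01 on day 3. The day 4.5 median was -0.42 without scaling and between 0.21 and 0.34 with quantile normalization, spike-in scaling, normexp correction, the authors' deposited values and dim members at their bound. On day 6 it was 0.59 with spike-in scaling and 0.73 over members well above background on all 5 arrays. The members moved both ways: of those measured on both arrays, 9 were at least 2-fold higher and 0 lower on day 1.5, and 6 higher and 5 lower on day 6. The desmosomal genes Pkp1 and Perp were at 2.85 and 2.04 on day 1.5 and at 3.29 and 2.93 on day 6, when Dsp, another desmosomal gene, was at 2.63. Keratin 18, Krt18, was at -1.84, P-cadherin, Cdh3, at -1.42 and the splicing factor gene Esrp2 at -1.59 on day 6. E-cadherin, Cdh1, was well above background only on day 6. Within a slide the medians were -0.04 for day 3 against day 1.5 and 0.30 for day 6 against day 4.5, the latter at -0.10 with normexp correction.

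The 25 measured members of the core pluripotency network had medians of 0.10, 0.10, -0.83 and -0.64. On day 4.5 the median lay just below the central 95% of random lists, at percentile 2.32, and on day 6 inside them, at percentile 10.5. The day 4.5 median is the value of Pou5f1, which was not well above background on day 0 or day 4.5 (processed signals 6.60 and 2.74). Of the 25 members, 15 were well above background on both arrays of that comparison. The day 3 median was -0.04 with median scaling and -0.25 with dim members at their bound. That value at the bound is again the one of Pou5f1, dim on days 0 and 3. With normexp correction, whose offset shrinks the differences of dim members, the medians of days 3, 4.5 and 6 were -0.020, -0.0023 and -0.018. On day 6, 7 members were at least 2-fold lower and 1 higher among those measured on both arrays. Mybl2, a cell cycle transcription factor, was at -2.09, Dnmt3l, a DNA methylation cofactor, at -1.88 and Klf5 at -1.39, and Lefty1, a Nodal inhibitor, at 1.35. Sall4 stood at -0.23, -0.44, -1.44 and -1.36. The 18 early pluripotency-associated genes had medians of 0.09, -0.19, -1.08 and -0.76, of which only day 4.5 lay outside the random lists (-0.85 to 0.32). With normexp correction days 4.5 and 6 were at -0.35 and -0.25. Etv5 was at 1.24 on day 6, Spry4, a feedback inhibitor of receptor tyrosine kinases, at -2.80 and Alpl, alkaline phosphatase, at -0.46. Within a slide the core network had medians of -0.13 for day 3 against day 1.5 and 0.09 for day 6 against day 4.5, the latter at -0.12 with normexp correction.

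**Figure D3:**
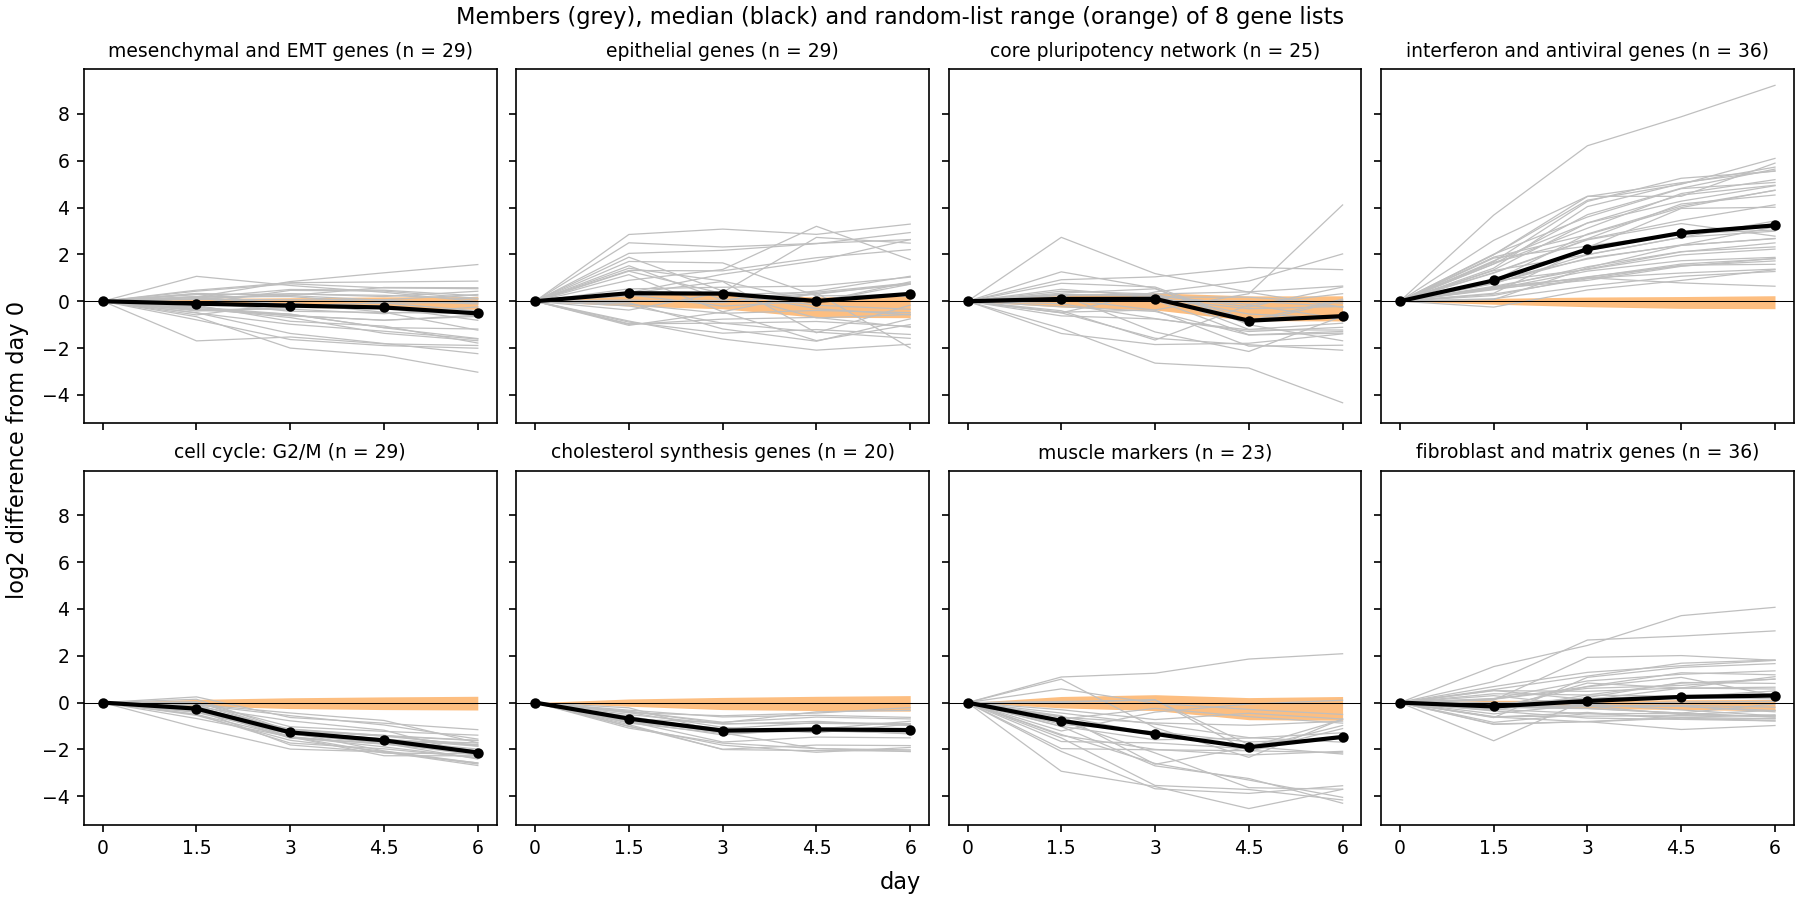
Log2 difference from day 0 for the members (grey) and the median (black) of 8 gene lists against day, with the central 95% of 10000 matched random lists in orange, and dim members at their measured values. The interferon median reaches 3.24 on day 6 and the G2/M median -2.13.

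Interferon and antiviral genes were the list with the largest shift. Their 36 measured members had medians of 0.89, 2.23, 2.91 and 3.24, where random lists on day 6 lay between -0.32 and 0.24. Of the 33 members measured on both arrays, 16 were at least 2-fold higher on day 1.5 and 32 on day 6, and 0 were lower on either day. Ifi44 was at 2.60 on day 1.5 and 5.90 on day 6, the ubiquitin-like modifier Isg15 at 2.01 and 5.07, Ifit1 at 1.99 and 5.57, and the nucleic acid sensor Zbp1 at 1.99 and 6.10. Within a slide the list had a median of 1.15 for day 3 against day 1.5 and 0.35 for day 6 against day 4.5, the latter at 0.68 without scaling. Inflammatory cytokines and chemokines had medians of -0.28, -0.27, -0.34 and -0.21 and moved both ways, and spike-in scaling turned the day 6 value to 0.07, while quantile normalization put day 1.5 at -0.11. Without scaling day 4.5 was at -0.77, and the members well above background on all 5 arrays were at -0.55 on day 3. Il6 and Cxcl5 were at -4.48 and -4.33 on day 6, and complement C3 at 5.00. Markers of macrophages and blood cells moved with the interferon list from day 3, at -0.17, 0.66, 0.85 and 1.14.

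The 29 mitosis (G2/M) genes had medians of -0.26, -1.27, -1.61 and -2.13. On day 1.5 1 of them was at least 2-fold lower, on day 3 25 and on day 6 all 29, where random lists lay between -0.32 and 0.27. Cks2 was at -2.69, the survivin gene Birc5 at -2.62 and Hmmr at -2.58 on day 6. The 29 S phase genes had medians of -0.30, -0.96, -1.03 and -1.25, and 23 were at least 2-fold lower on day 6, among them Uhrf1 (-2.39) and Cdc6 (-2.16). Within a slide the G2/M median was -1.03 for day 3 against day 1.5 and -0.45 for day 6 against day 4.5, and the S phase median -0.63 and -0.24. Without scaling the G2/M median for day 6 against day 4.5 was -0.12. For that step leaving out scaling moved the median of all genes from 0.011 to 0.33, a shift larger than the S phase value. The p53 and senescence list, 29 genes, was at 0.44, 0.25, 0.12 and 0.17, outside the random lists on days 1.5 and 3, without scaling the day 4.5 value was -0.32, and with median scaling the day 3 value was 0.11. Spike-in scaling put days 4.5 and 6 at 0.32 and 0.44. Igfbp3 was at 2.86 and Plk2 at -2.33 on day 6.

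Genes of biosynthesis and energy metabolism were also lower. The 20 cholesterol synthesis genes had medians of -0.69, -1.20, -1.15 and -1.17, and 0 members were at least 2-fold higher on any of the 4 days. On day 6 Cyp51 was at -2.09 and Fdps at -2.07. The 23 glycolysis genes were at -0.35, -0.74, -0.69 and -0.77, with Eno1 and Pgk1 at -1.65 and the lactate transporter Slc16a3 at -1.71 on day 6. The 34 Myc-linked ribosome biogenesis genes were at -0.43, -0.72, -0.66 and -0.62, with Odc1, the first enzyme of polyamine synthesis, at -1.58 on day 6. All 3 of these lists lay below the random lists on every day. The 35 oxidative phosphorylation genes were at -0.07, -0.30, -0.36 and -0.42 and lay below the random lists from day 3, with Cycs, cytochrome c, at -1.27 on day 6. Spike-in scaling put their day 1.5 median at 0.0033. The housekeeping control genes were about as low, at -0.28, -0.41 and -0.43 on days 3, 4.5 and 6. Quantile normalization put glycolysis at -0.34 on day 4.5 and -0.38 on day 6. Spike-in scaling put oxidative phosphorylation at -0.18, -0.16 and -0.15 on days 3, 4.5 and 6 and ribosome biogenesis at -0.34 on day 6. For day 3 against day 1.5, within a slide, the medians were -0.53 for cholesterol, -0.35 for glycolysis, -0.30 for ribosome biogenesis and -0.23 for oxidative phosphorylation, and for day 6 against day 4.5 they were -0.04, 0.07, -0.00087 and -0.07.

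The members of the fibroblast and matrix list moved apart. On day 6, 10 of the 36 were at least 2-fold higher, 0 were lower and 26 were within 2-fold. The medians were -0.17, 0.07, 0.24 and 0.30, below the random lists on day 1.5 and above them on days 4.5 and 6, and the constant shifts of other scalings put day 4.5 at -0.20 (unscaled) or 0.44 (spike-in), day 3 at -0.08 (median scaling) and day 6 at 0.57 (spike-in). Elastin, Eln, was at 4.07 on day 6, the proteoglycan decorin, Dcn, at 3.06 and Mfap5 at 1.82, while Thy1, a fibroblast surface marker, was at 0.30 and Pdgfrb at -0.98. The collagen genes Col6a2 and Col5a2 were at -0.78 and -0.69. Within a slide the medians were 0.16 for day 3 against day 1.5 and 0.03 for day 6 against day 4.5. The 25 genes of TGF-beta signalling had medians of 0.03, -0.0016, -0.0122 and -0.0243, with members on both sides, and spike-in scaling put days 3, 4.5 and 6 at 0.11, 0.19 and 0.25. Pmepa1, a target of the pathway, was at 1.70 on day 6. Id1 was at 2.67 on day 3 and 0.67 on day 6, and Tgfb3 at -1.19 on day 6. The 31 Bmp and Wnt genes had medians of 0.24, 0.23, -0.07 and -0.23, and spike-in scaling turned the day 4.5 and day 6 values to 0.13 and 0.04. On day 4.5 the alternatives ran from -0.50 (unscaled) to 0.34 (dim members at their bound). With normexp correction day 1.5 was at 0.065 and day 3 at 0.11. Wnt2 was at 3.95 and Ccn5 at -3.54 on day 6.

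The other lists held markers of other cell types. The 23 muscle markers had medians of -0.78, -1.34, -1.91 and -1.47, below the random lists on all 4 days, with Acta1 at -4.05, Myl1 at -3.70 and Cnn1 at -4.30 on day 6 and cardiac troponin Tnnt2 at 2.09. For day 3 against day 1.5, within a slide, the muscle median was -0.58, and for day 6 against day 4.5 it was 0.16. With normexp correction the muscle medians against day 0 were -0.49, -0.71, -0.71 and -0.73. Of the 21 macrophage and blood cell markers, 13 were at least 2-fold higher and 1 lower on day 6. The embryonic globin gene Hbb-y was at 6.34, Laptm5 at 2.57 and lysozyme Lyz2 at 2.03, with Cd74 at -1.44. Within a slide that list had medians of 0.83 and 0.20, and its day 6 median was 0.73 with normexp correction. The 18 endothelial markers were at 0.62, 0.50, -0.0102 and -0.17, and spike-in scaling turned the day 4.5 and day 6 values to 0.19 and 0.10. On day 4.5 the alternatives ran from -0.45 (unscaled) to 0.39 (members well above background on all 5 arrays). With normexp correction days 1.5, 3 and 6 were at 0.20, 0.22 and 0.14, and without scaling day 6 was at -0.28. Plvap was at 3.90, Emcn at -3.62 and Ecscr at -2.82 on day 6.

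The 25 neural and glial markers had medians of 0.31, 0.18, 0.33 and 0.41. Over the alternatives they ran from 0.033 (normexp correction) to 0.75 on day 1.5, from -0.017 (normexp correction) to 0.58 on day 3, from -0.11 (unscaled) to 0.66 on day 4.5 and from 0.26 (mean over probes) to 1.05 on day 6, with all 4 upper values from the 17 members well above background on all 5 arrays. S100b was at 4.75 and Syt1, a synaptic vesicle protein gene, at 4.32 on day 6, and Tubb3 at -2.80. The 27 keratinocyte markers had medians of 0.48, 0.56, 0.05 and 0.41. Alternatives ran from -0.39 (unscaled) to 0.41 (dim members at their bound) on day 4.5. On day 6 they ran from -0.04 (dim members at their bound) to 0.68 (spike-in scaling). The 0.41 at the bound on day 4.5 was also the neural list's value at the bound. It is the difference between the lowest levels well above background on days 4.5 and 0, and says nothing about the markers. With normexp correction days 1.5, 3 and 6 were at 0.23, 0.085 and 0.24. Krt14 was at 2.24 and Krt5 at -2.08 on day 6, and the gap junction gene Gjb2 at -3.13. The 22 adipocyte, cartilage and bone markers were at -0.11, -0.28, -0.49 and -0.50, with the fatty acid receptor Cd36 at 2.42 and aggrecan, Acan, at -2.45 on day 6. The 16 endoderm, mesoderm and trophoblast markers, like the adipocyte, cartilage and bone markers inside the random lists on all 4 days, were at 0.30, -0.19, -0.58 and -0.84, with Gata2 at -1.26 on day 6. With normexp correction the day 4.5 medians of the adipocyte and endoderm lists were 0.10 and 0.09, and the day 1.5 median of the latter was -0.04. Their day 6 medians were then -0.096 and -0.062, while without scaling their day 4.5 medians were -0.92 and -1.02.

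Regulators of chromatin and DNA methylation, 41 genes, had medians of -0.08, -0.20, -0.17 and -0.14, and spike-in scaling turned the day 4.5 and day 6 values to 0.03 and 0.14, while without scaling they were -0.61 and -0.25. Ezh1 was at 1.75 and the de novo methyltransferase Dnmt3a at 1.22 on day 6, and the histone methyltransferase gene Suv39h2 at -1.48 on day 4.5. The 29 unfolded protein and stress response genes had medians of -0.08, 0.06, -0.20 and -0.50, of which day 6 lay below the random lists, median scaling put day 3 at -0.08, and spike-in scaling put day 6 at -0.23. The immediate-early genes Fos and Egr1 were at 1.39 and 1.04 on day 1.5 and at -0.49 and -0.63 on day 6, and Hmox1, heme oxygenase, was at 1.50 and Chac1 at -2.24. As controls, 29 ribosomal protein genes had medians of 0.06, -0.08, -0.22 and -0.35, inside the random lists on all 4 days but below them for day 4.5 against day 3 (percentile 0.61) and day 6 against day 4.5 (percentile 1.64), with 0.06 on day 3 under quantile normalization and 0.0108 on day 4.5 in the authors' deposited values. Spike-in scaling put the ribosomal protein genes at -0.017 on day 4.5 and -0.073 on day 6. The 18 housekeeping genes were at -0.08, -0.28, -0.41 and -0.43. They lay below the random lists on day 4.5, at percentile 1.49, and for day 3 against day 1.5, at percentile 0.86. Spike-in scaling put their days 4.5 and 6 at -0.21 and -0.16, and unscaled signals put day 4.5 at -0.85. Among their members Tfrc, the transferrin receptor, was at -2.35 and B2m at 1.60 on day 6. The delivered factors as a list of 4 genes were at 0.53, 0.94, 0.57 and 0.79. Pou5f1 was not well above background on day 0, and the Myc value is from 1 of the disagreeing probes. The list median lay midway between Pou5f1 and Sox2 on day 1.5 and between Pou5f1 and Myc on day 3. On days 4.5 and 6 the list median lay midway between Sox2 and Myc. It was 0.030 on day 1.5 with normexp correction, and 0.62, 0.22 and 0.42 on days 3, 4.5 and 6 with the mean over probes. On day 4.5 it was 0.13 without scaling, 0.89 with dim members at their bound and 1.38 over the 3 members well above background on all 5 arrays.

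Of the lists whose place against day 0 is not given above, inflammatory genes lay below the random lists on day 1.5. Bmp and Wnt genes and endothelial markers lay above them on days 1.5 and 3, keratinocyte markers on days 1.5, 3 and 6, neural markers on days 1.5, 4.5 and 6, macrophage and blood cell markers from day 3 and the delivered factors on day 3. TGF-beta genes and chromatin regulators lay inside them on all 4 days.

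For the remaining lists the within-slide medians, first for day 3 against day 1.5 and then for day 6 against day 4.5, were as follows. Early pluripotency-associated genes had -0.10 and 0.11, p53 and senescence genes -0.09 and -0.03, and inflammatory genes 0.15 and -0.19. TGF-beta genes had 0.05 and 0.0053, Bmp and Wnt genes 0.20 and -0.09, and endothelial markers -0.0151 and 0.08. Neural markers had -0.15 and 0.11, keratinocyte markers 0.04 and 0.115, adipocyte, cartilage and bone markers -0.08 and -0.17, and endoderm, mesoderm and trophoblast markers -0.17 and -0.0075. Chromatin regulators had -0.09 and 0.010, stress response genes -0.23 and -0.13, ribosomal protein genes -0.13 and -0.13, and housekeeping genes -0.25 and -0.0056. Alternatives for steps are reported only for the mesenchymal, epithelial, core pluripotency, interferon and G2/M lists. For day 6 against day 4.5 leaving out scaling moved the median of all genes from 0.011 to 0.33. That shift is larger than any value of these remaining lists at that step, so the sign of the negative ones depends on scaling.

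In the counts over the course that follow, a dim value was raised to the lowest level well above background on its array where it lay below that level. Those levels differed between arrays, with processed signals of 8.46 on day 1.5 and 11.7 on day 4.5 before scaling. For genes dim on some days, a high, low or middle-day extreme can therefore come from these levels. Over the whole course, 5558 genes (35.2%) had a range of at least 2-fold. Of these 2223 were highest on day 0, 915 on day 1.5, 439 on day 3, 414 on day 4.5 and 1567 on day 6. The values of 903 genes were higher at every step and those of 981 lower at every step. On a middle day 317 genes were at least 2-fold above both ends of the course and 77 below both. Across the 13218 genes well above background on all 5 arrays, Pearson's r with day 0 was 0.978 on day 1.5, 0.956 on day 3, 0.941 on day 4.5 and 0.926 on day 6. These are correlations across genes, which are not independent replicates. The first principal component held 79.0% of the variance and ordered the 5 arrays by day.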

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

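No test in this part was chosen after its result was seen, since only counts are given. Probes without a gene symbol enter no count of genes and no list above, yet many of them differed from day 0. Of 6559 such probes well above background on both arrays, 175 were at least 2-fold higher and 261 lower on day 1.5. On day 3, 589 of 6526 were higher and 419 lower, on day 4.5, 638 of 5666 were higher and 679 lower, and on day 6, 709 of 6179 were higher and 980 lower. What these probes measure was not examined, and the cause was not tested.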

How the results depend on the processing

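The normexp correction was the alternative chosen after the data were seen, and all others were planned. No paired analysis was possible because each day had 1 array, and for the same reason no replicate was left out and no slide block was fitted. Of 199 alternatives to the 7 counts and the 12 medians of the mesenchymal, epithelial and core pluripotency lists against day 0, 133 stayed within the limits set (1.5 times for a count, and for a median 0.162, the square root of 2 times the mean SD of single spike-in probes, which is no error of a median), 65 moved beyond them and 1 reversed, where reversed means that a median outside the central 95% of random lists changed sign. Any change of sign, medians inside that range included, occurred in 5. Of 1035 alternatives to other list medians, 847 stayed, 182 moved and 6 reversed, and 52 changed sign. Of 6909 alternatives to differences of named genes, 5666 stayed within the software's spot error, 1243 moved and 0 reversed a difference of at least 2-fold. The sign of any difference changed in 205. Unmatched random lists moved 7 of 112 percentiles across the central 95% range. Members that are not well above background have only a bound. A member dim on both arrays can carry the difference between the arrays' lowest levels well above background. Medians and reversals at the bound therefore partly reflect those levels. Median, spike-in and no scaling shift all genes of a comparison by 1 constant, so the changes they make to a median, reversals included, are that constant and leave its place among random lists as it was. Except there, and where a threshold, the unit or added probes without a symbol change the count, the cause was not tested.

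Counts are given in the order day 1.5, 3, 4.5 and 6 against day 0, then day 3 against day 1.5, day 4.5 against day 3 and day 6 against day 4.5. The main counts were 1080, 2005, 2678, 3400, 696, 409 and 194. Normexp correction gave 513, 1230, 1668, 2155, 302, 87 and 55. The 1.5-fold threshold gave 2653, 4530, 5296, 6212, 2096, 1348 and 877, and the 3-fold threshold 368, 735, 1030, 1439, 183, 59 and 40. Counting probes, those without a gene symbol included, gave 1823, 3742, 5010, 6388, 1205, 878 and 369. On day 6 against day 0, 709 higher and 980 lower ones had no symbol. These counts therefore mix the change of unit with added probes. Without the filter on dim probes the counts that moved were 1861 (day 1.5), 4210 (day 4.5), 1106, 1408 and 748 (the 3 steps). Without scaling the last 2 steps had 1153 and 365, and with bounded differences added they had 645 and 353.

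The mesenchymal median was -0.065 on day 4.5 and -0.24 on day 6 with spike-in scaling, -0.70 on day 4.5 without scaling and -0.47 on day 4.5 with the mean over probes. Without scaling its day 6 against day 4.5 value reversed to 0.17. The epithelial median on day 4.5 was 0.25 with quantile normalization, 0.21 with spike-in scaling, -0.42 without scaling, 0.21 with normexp correction, 0.23 in the authors' deposited values and 0.34 with dim members at their bound. On day 1.5 it was 0.055 with normexp correction and 0.061 at the bound, and on day 3 it was 0.011 with normexp correction, 0.041 at the bound and 0.060 over members well above background on all 5 arrays. On day 6 it was 0.59 with spike-in scaling, 0.73 over those members, and reversed to -0.21 at the bound. Its day 4.5 against day 3 value reversed to -0.40 without scaling and its day 6 against day 4.5 value to -0.098 with normexp correction.

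The core pluripotency median on day 4.5 was -0.63 with spike-in scaling, -1.27 without scaling, -0.0023 with normexp correction, -0.32 at the bound and -0.55 over members well above background on all 5 arrays. On day 6 it was -0.43 with quantile normalization, -0.36 with spike-in scaling, -0.018 with normexp correction, -0.44 in the authors' deposited values and -0.24 at the bound, and on day 3 it was -0.25 at the bound. Without scaling the day 4.5 medians of the fibroblast and neural lists reversed to -0.20 and -0.11, and the keratinocyte median of day 6 reversed to -0.037 at the bound.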

Other observations

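The tests on the Myc probes and the interferon genes, the resampling of list members and the percentile of the pluripotency members well above background were chosen after the results were seen, and the other tests on the pluripotency genes before. Among genes with a bound only, 2 genes of striated muscle were far above day 0 while the muscle list as a whole was lower. Hrc, which encodes a calcium-binding protein of the sarcoplasmic reticulum, was at least 96.0-fold higher on day 3 and at least 195-fold on day 6. Myo18b, an unconventional myosin of muscle, was at least 43.7-fold higher on day 3 and at least 179-fold on day 6.

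The 3 Myc probes changed in different directions after day 1.5, when c-Myc virus was first delivered. Their changes from day 0 to day 1.5 lay within 0.16 of each other, and from day 1.5 to day 3, within a slide, they were -1.05, 1.65 and 2.36. The gap of 2.70 between the lower probe and the nearer of the others was 13.2 times the software's spot error of a difference, which argues against spot noise. Measured replicate spots had a root mean square SD of 0.138 on the array where it was highest. A candidate explanation is that 2 of the probes also detect the delivered transcript while the third detects the cell's own Myc only. The values it needs are there, but probe positions relative to the delivered sequence are not known here, so it stays a hypothesis.

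Interferon and antiviral genes were higher on each later day. Slide or scan differences as the whole cause are argued against by the within-slide median of 1.15 for day 3 against day 1.5, where the central 95% of random lists reached up to 0.082 and the median had an SD of 0.20 over resampled members. A larger share of macrophages with no change in any cell is less clearly argued against. On day 6 the lower quartile of the interferon list (2.14) lay 0.559 above the upper quartile of the macrophage and blood cell list (1.58). The SD over resampled members was 0.43, so the margin is little more than its SD. The latter list also mixes globin and macrophage genes, with Hbb-y at 6.34 and Lyz2 at 2.03. These values lean against that explanation and do not settle it. A response to the virus and time in culture cannot be told apart, because there were 0 arrays in addition to the 1 infected series per day. Either may contribute.

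The core pluripotency list read lower on days 4.5 and 6, both on the third slide, although the day 6 median lay inside the random lists (percentile 10.5). A signal-dependent offset between slides may contribute: over 5 bins of mean level the median of day 4.5 against day 3 was -0.19 in the dimmest genes and 0.023 in the brightest. Under quantile normalization the day 4.5 median was still -0.71 but at percentile 2.55 of random lists, which leaves this open. Members near background stay open as well, since the 15 of 25 members well above background on all 5 arrays had a median of -0.55 with an SD of 0.48 over resampled members, which does not set it apart from -0.42, 0.5 times the main median. It lay at percentile 7.5 of random lists drawn from genes of that kind. Normexp correction put the medians of both days at -0.0023 and -0.018. Its offset of 50 shrinks the differences of dim members whatever their cause, so these medians decide nothing. The main day 4.5 median was itself the value of Pou5f1, which was not well above background on either array. These explanations and a biological change between days 3 and 4.5 cannot be told apart, because slide and day coincide.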
